A study of Mus musculus with 12 samples.

How the data were processed

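RNA of single livers was measured on oligonucleotide arrays with 2 dyes, after amino-allyl labelling of total RNA extracted with Trizol. Each of the 12 samples compared 2 livers on 2 arrays with the dyes exchanged. The deposited array files held an intensity per channel (green for Cy3, red for Cy5), raw and processed, per the file headers, and the authors' software had already subtracted the background and normalized the dyes of the processed values. The same deposited files held a log10 ratio of red over green, limited to 2 in either direction. The deposited table of the series held a log2 ratio of the first-named over the second-named liver, per the labels, averaged by the authors over both dye-swapped arrays in Rosetta Resolver. The files lacked the separate foreground and background columns that had been planned for, so the fallback written before the data were examined was used: the processed, background-corrected intensities.

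Of 25760 spots per array, 2186 were controls, among them 156 spots of 26 negative control reporters, and 23574 were gene probes. Symbols came from the platform table, brought up to date by gene identifier, and from reference tables of the assembly GRCm38.p6, which were used for names and, in the closing section, for the chromosome of a gene and the distance of genes on chromosome 11 from Stat5a: 20447 probes had 1 symbol, 50 had several and 3077 had none, for 18339 distinct symbols. Log2 ratios were loess-normalized within each array with control spots at weight 0 (limma 3.58.1 in R 4.3.3), spots marked as failed were set to missing, each array was turned to the direction of its label, and both arrays of a sample were averaged. Probes were kept if their mean log2 intensity exceeded the 95th percentile of the negative controls (-5.19), which left 19805, and tested if each group had at least 2 values, which left 19487. Between 64 and 328 spots of the red channel and 34 to 283 of the green channel were saturated per array.

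A mean per group was fitted with limma (lmFit and eBayes) over all 12 samples, with 8 residual and 1.92 prior degrees of freedom. Each group mean was tested against 0, and both sex comparisons and both genotype comparisons were tested against each other, all with Benjamini-Hochberg adjusted p under 0.05. Genes with several probes were represented by the probe with the highest mean intensity. A list of 33 gene groups, namely sex-biased genes, the growth hormone axis, sex chromosome genes, metabolic families, stress and immune responses, and markers of other cells, was written before the data were examined. Each was counted over all tested probes and adjusted over the list alone, and tested with fry of limma, whose directional p asks whether the genes move one way on balance and whose mixed p whether they change in either direction. Genes named in the text were drawn from Stat5a and Stat5b, the 8 largest rises and the 8 largest falls of each comparison with the same direction in 3 of 3 samples, and members of the lists, those of largest change first and at most 4 per list and comparison. Serpina1a, Cyp4a12b and Cd68 lie outside this rule, as do genes that only the closing section names, and were chosen after their values were seen. A fold against a channel below background is given as a lower bound from the 95th percentile of the negative controls.

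The labels do not say whether a replicate number marks the same animals in the 4 groups. The values show that it does: the 4 ratios of one number closed the loop of comparisons with a standard deviation of 0.18 to 0.24 (log2) across probes, and mixed numbers with 0.37 to 0.81, over 81 combinations. Deviations from the group mean correlated at 0.13 to 0.63 between samples of one number that share a kind of liver. The 12 ratios thus share animals and are not independent, although the fit of the text takes them as such. The 5187 and 5278 probes called between the sexes rest on that fit. It has 8 residual degrees of freedom, while a model of single animals has 6. The fit of the text has no such block, as was fixed before, and fits with the number as a block, as an additive term or in a model of the loop, are given where they ended or gave a call of a named gene. The additive term takes the shift shared by the samples of one number out of the residual. That shift between animals then does not enter the SE of a group mean, so p-values with this block can be too small.

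The procedure was tested on simulated data. With 200 changed probes of 16187, the fit recovered 59.7% of 1.5-fold, 86.6% of 2-fold and 100% of 4-fold genotype differences in females, and 56.7%, 82.1% and 92.4% of sex differences in wild-type liver, with 0 of wrong sign. Among 15987 unchanged probes these fits gave 16 false calls for genotype and 26 for sex. These stood beside 40, 58 and 66 recovered probes for genotype and 38, 55 and 61 for sex. False calls were thus a larger share of all calls than the adjusted p threshold aims at. The shares recovered hold for the number of changed probes simulated and do not give the power of the real genotype comparison in females. That comparison had 2 calls, and Stat5a, 6.29-fold lower, was not among them (limma adjusted p = 0.080). With no effect, 20 simulations gave 0.4 to 0.8 calls on average and at most 5. Alternatives were log ratios of the software, median centring, no filter, a stricter filter (above background in both channels of at least 22 of 24 arrays), only the samples of the groups compared, the replicate block as an additive term and as a model of the loop, the deposited table, a fold of at least 1.5 besides, arrays of one dye orientation, and leaving out each sample. Normexp (offset 50) on raw intensities, the removal of both samples of 1 animal and the mean knockout effect of both sexes were added after the data had been seen. A run without background correction was not made: the files lack separate foreground and background columns, and the raw intensities were used with normexp only. A block for slide or scan date could not be made, since the files hold no dates. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.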

Results

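Liver RNA of 8-9 week old mice of the strain 129JxBlack Swiss was compared on 2-colour oligonucleotide arrays, with wild-type animals and animals lacking STAT5a, a transcription factor that acts downstream of growth hormone and prolactin receptors. The 12 samples fell into 4 groups of 3: females over males in wild-type liver, females over males in knockout liver, knockout over wild-type in female liver and knockout over wild-type in male liver. Each sample was the ratio of 2 livers on 2 dye-swapped arrays, 24 arrays in all. Between 63.1% and 84.5% of the gene probes of an array channel lay above the negative control spots, and 71 to 1715 spots per array were marked as failed. The number of samples per group, 3, limits the precision of every ratio. Of 23574 gene probes, 19487 were tested, and 15618 genes were represented by a tested probe. All log2 values are group means with the standard error (SE) of the limma fit and n = 3 samples, unless another n is given. The files name no genome build, and positions were used only in the closing section, from the assembly GRCm38.p6.

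The comparison of wild-type females with wild-type males asked which liver transcripts differ between the sexes. Large female excesses were seen in the sulfotransferase Sult3a1, with a log2 ratio of 7.19 (SE 0.33) or 146-fold, the peroxisomal hydroxyacid oxidase Hao2 at 6.88 (SE 0.33) and the transporter gene Slc22a26 at 6.30 (SE 0.21). On the male side stood the Y-linked RNA helicase gene Ddx3y at -6.02 (SE 0.45; above background on 4 of 6 female channels). The scavenger receptor gene Scara5 was at -5.81 (SE 0.70; above background on 1 of 6 female channels), and the size is uncertain for both. The steroid dehydrogenase Hsd3b5 was at -5.55 (SE 0.41) and the cytochrome P450 Cyp2d9 at -5.31 (SE 0.64). Each of these genes had the same direction in 3 of 3 samples, with adjusted p from 1.5e-06 for Slc22a26 to 5.5e-04 for Scara5.

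In that comparison 5187 of 19487 probes passed the limma test at an adjusted p under 0.05, 2509 of them higher in females and 2678 higher in males. With a fold change of at least 1.5 besides, 1224 were higher in females and 736 in males. Further female-biased genes by the naming rule were Sult3a2 (log2 6.27, above background on 1 of 6 male channels), C730007P19Rik (5.96), A1bg (5.76) and Sult2a2, which was at least 19.5-fold higher because its male signal lay below background. Further male-biased genes were Eif2s3y (-5.27, above background on 2 of 6 female channels), Susd4 (-4.65) and Cyp4a12a (15.9-fold), the enzyme that makes 20-HETE from arachidonic acid. Elovl3, a fatty acid elongase, was at least 7.63-fold lower in females, whose signal lay below background. Stat5a itself had a log2 ratio of 0.05 (SE 0.37, adjusted p = 0.93) and Stat5b of 0.09 (SE 0.06, adjusted p = 0.29), the latter from a dim probe above background on 2 of 6 female and 1 of 6 male array channels.

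The textbook lists of sex-biased liver genes followed their names in wild-type liver. Of 28 tested male-biased genes, 24 were higher in males (24 adjusted over the list alone), 0 were higher in females (1 adjusted over the list alone) and 4 did not pass. Of 39 female-biased genes, 29 were higher in females (30 adjusted over the list alone) and 1 was higher in males (2 adjusted over the list alone). All 4 tested Y-linked genes were higher in males, Ddx3y, Eif2s3y and Kdm5d most, and Kdm5d was at least 4.34-fold lower in females. Of 4 X-linked dosage genes, 3 were higher in females (3 adjusted over the list alone): Ddx3x at 1.17, Eif2s3x at 0.87 and Kdm6a, at least 1.81-fold higher. The directional fry test of limma, adjusted over 33 lists, gave 2.5e-06 for the male-biased and the female-biased list.

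Drug and steroid metabolism genes went both ways. Among 82 cytochrome P450 genes, 18 were higher in females and 20 in males (18 and 20 adjusted over the list alone), from Cyp2b13 at 4.31 (SE 0.99) and Cyp3a16 at 3.78 (SE 0.41) to Cyp2d9. Of 14 sulfotransferases, 8 were higher in females (10 adjusted over the list alone) and 0 in males, with a fry adjusted p of 2.9e-04. Of 21 glutathione S-transferases, 9 were higher in females (10 adjusted over the list alone) and 2 in males (2 adjusted over the list alone), with Mgst3 at 2.14, Gstt3 at 1.61 and Gstp1 at -0.88. The 3 tested major urinary protein genes, which encode pheromone carriers, were higher in males (3 adjusted over the list alone), with Mup3 at -2.19, Mup4 at -1.66 and Mup1 at -1.47. Among 40 serpins, 5 were higher in females and 11 in males (5 and 12 adjusted over the list alone), with the largest values in Serpinb1a at 3.31 and Serpina6, the corticosteroid-binding globulin, at 1.60. Of 13 UDP-glucuronosyltransferases, 2 were higher in each sex (2 each adjusted over the list alone).

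Among 18 organic ion transporters, 6 were higher in females and 2 in males (6 and 2 adjusted over the list alone), with Slco1a4 at 2.21, Abcb1a at 2.20 and Abcg2 at -1.17. Of 13 bile acid synthesis genes, 2 were higher in females and 4 in males (2 and 4 adjusted over the list alone). Cyp7b1, the oxysterol hydroxylase of the acidic pathway, was at -2.74 (SE 0.44), while Akr1d1 was at 1.68 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 1.51 (SE 0.40). Of 18 fatty acid synthesis genes, 4 were higher in females and 0 in males (4 and 0 adjusted over the list alone), among them Pnpla3 at 2.99 and Elovl5 at 1.30. Of 26 genes of fatty acid oxidation and PPARA targets, 9 were higher in females and 2 in males (10 and 2 adjusted over the list alone), with Acot3 at 3.16, the fatty acid translocase Cd36 at 2.89 and Vnn1 at 2.52. Of 22 acute-phase genes, 2 were higher in females and 6 in males (2 and 6 adjusted over the list alone). Saa1 was at -2.12 and Saa3 at -2.02, and Hamp, which encodes the iron hormone hepcidin, was at 1.39.

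Single markers of other cells also differed between wild-type females and males. Of 11 markers of Kupffer and other macrophages, 6 were higher in females and 1 in males (7 and 1 adjusted over the list alone), with Adgre1 at 1.82, Vsig4 at 1.78 and Cd5l at 1.47, whose adjusted p of 0.040 became 0.057 with the replicate number as a block and 0.067 in a model of the loop of comparisons (loop model below). Of 19 interferon response genes, 4 were higher in females (1 adjusted over the list alone), with Ifit3 at 1.63. The medians of both lists came mainly from 1 sample: in replicate 2 they were 2.08 and 2.08, against 0.61 and 0.37 in replicate 1 and 0.33 and 0.20 in replicate 3. Of 9 lymphocyte genes, 3 were higher in males (3 adjusted over the list alone), among them Lck at -0.86 and Cd3e at -0.64. The fry test of that list pointed to males (adjusted p = 0.0039), its mean was -0.09 and its median was 0.15. Of 12 early response genes, 4 were higher in females (5 adjusted over the list alone), with Dusp1 at 1.65 and Gadd45b at 1.60. Of 16 clock genes, 3 were higher in females (2 adjusted over the list alone), with Bhlhe40 at 1.51 and Hlf at 0.96. The fry adjusted p was 0.066 for macrophages, 0.18 for interferon response, 0.051 for early response and 0.27 for clock genes.

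The growth hormone and STAT5 axis held 4 genes higher in wild-type females and 3 in wild-type males among 25 (4 and 4 adjusted over the list alone; mixed fry adjusted p = 2.3e-06), with Socs2, a feedback inhibitor of cytokine signalling, at 2.70 (SE 0.85). Cholesterol synthesis held 0 and 2 of 23 genes (0 and 2 adjusted over the list alone), and the cell cycle held 2 and 0 of 17 genes (2 and 0 adjusted over the list alone). Heat shock and unfolded protein genes held 1 in each direction of 15 (1 and 0 adjusted over the list alone), and gluconeogenesis held 0 of 11 (0 adjusted over the list alone). Neutrophils, endothelium and stellate cells each held 1 gene higher in females (1 adjusted over the list alone), among 4, 7 and 7 tested genes. Blood, adipose tissue and exocrine pancreas each held 1 gene higher in males (1 adjusted over the list alone), among 3, 5 and 7 genes. Antigen presentation and bile duct held 0 among 4 and 6 genes (0 adjusted over the list alone). In the fit on these 3 samples alone 1753 probes passed and, among others, the calls of Akr1d1, Elovl5, Gstp1, Mup4 and Serpinb1a ended, and without replicate 2 or replicate 3 of this group 3167 or 3351 passed. Without 1 or another of the 3 samples the calls of Adgre1, Bhlhe40, Cd5l, Cyp2b13, Dusp1, Gstt3, Hamp, Hlf, Ifit3, Mup1, Mup3, Pnpla3, Saa1, Saa3, Socs2 and Vnn1 ended, of which all but Bhlhe40, Cyp2b13, Pnpla3, Saa1 and Saa3 ended on the 3 samples alone too, and that of Cyp7a1 ended without any of them (adjusted p up to 0.12). Of 141 genes with several called probes, 27 had probes called in opposite directions.

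The comparison of knockout females with knockout males asked the same question in livers without STAT5a. Large female ratios were again seen in Sult3a1, at a log2 ratio of 6.54 (SE 0.33), Hao2 at 5.95 (SE 0.33) and Sult3a2 at 5.89 (SE 0.41; above background on 2 of 6 male channels). In males Ddx3y stood at -5.87 (SE 0.45; above background on 4 of 6 female channels). Eif2s3y was at -5.49 (SE 0.42; above background on 3 of 6 female channels), Hsd3b5 at -5.24 (SE 0.41) and Cyp2d9 at -5.18 (SE 0.64). All were in the same direction in 3 of 3 samples, with adjusted p from 1.0e-05 for Sult3a1 to 4.4e-04 for Cyp2d9. Saa1, an acute-phase apolipoprotein, was at -4.17 (SE 0.47).

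Here 5278 of 19487 probes passed the limma test, 2666 higher in females and 2612 in males, and 1174 and 742 of them had a fold change of at least 1.5. Further female-biased genes were A1bg (log2 5.56), C730007P19Rik (5.47) and Slc22a26 (5.28). Further male-biased genes were Scara5 (-5.05), Susd4 (-4.13), Cyp4a12a (-3.52) and Elovl3, at least 6.54-fold lower in females, whose signal lay below background. Stat5a had a log2 ratio of -0.43 (SE 0.37, adjusted p = 0.41), and no value is given for Stat5b, whose probe lay above background on 1 of 6 female and 0 of 6 male array channels. Of 28 male-biased genes, 19 were higher in males (19 adjusted over the list alone) and 0 in females, and of 39 female-biased genes, 28 were higher in females (31 adjusted over the list alone) and 2 in males (2 adjusted over the list alone). All 4 Y-linked genes were higher in males, and of 4 X-linked dosage genes 3 were higher in females (3 adjusted over the list alone), with Ddx3x at 1.26 and Eif2s3x at 1.21.

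Among the metabolic lists of knockout liver, 17 cytochrome P450 genes were higher in females and 12 in males (18 and 13 adjusted over the list alone). Sulfotransferases held 8 higher in females and 1 in males (10 and 2 adjusted over the list alone), and glutathione S-transferases 10 and 2 (14 and 2 adjusted over the list alone), with Gstt3 at 2.39, Mgst3 at 1.64 and Gstp1 at -1.36. Cyp7a1 was at 2.47 (SE 0.40) and Cyp7b1 at -2.52 (SE 0.44), in a bile acid list with 2 genes higher in females and 3 in males (3 and 3 adjusted over the list alone). Slco1a4 was at 2.14 and Abcg2 at -1.52, among 5 transporters higher in females and 3 in males (7 and 3 adjusted over the list alone). Fatty acid oxidation and PPARA targets held 8 genes higher in females and 0 in males (9 and 1 adjusted over the list alone), with Acot3 at 2.86 (n = 2), and fatty acid synthesis held 4 and 0 (4 and 0 adjusted over the list alone). Of 3 major urinary protein genes, 2 were higher in males (2 adjusted over the list alone), Mup3 2.82-fold and Mup4 1.94-fold, of which Mup3 was not called in the loop model (adjusted p of 0.048, then 0.071).

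Acute-phase genes were higher in knockout males in 5 of 22 cases and in females in 1 (5 and 1 adjusted over the list alone), with Saa3 at -4.12, Saa2 at -3.08 and Hp, the haptoglobin gene, at -1.21. Early response genes held 3 of 12 higher in females (3 adjusted over the list alone; fry adjusted p = 0.026), with Gadd45b at 2.74 and Dusp1 at 2.19. Lymphocyte genes held 4 of 9 higher in males (4 adjusted over the list alone; fry adjusted p = 6.1e-04). Macrophage markers and interferon response genes held 0 of 11 and 0 of 19 (0 adjusted over the list alone), with fry p of 0.72 and 0.96 before adjustment. Cholesterol synthesis held 3 genes higher in females and 2 in males (2 and 1 adjusted over the list alone), with Insig1 at 1.01. The bile duct list held 1 gene in each direction (1 and 1 adjusted over the list alone), with the osteopontin gene Spp1 at -2.29. Serpins held 3 genes higher in females and 6 in males, the growth hormone axis 4 and 3, and the clock 2 and 0 (as many adjusted over the list alone). On these 3 samples alone 2992 probes passed and the calls of Hp and Spp1 ended, and without replicate 1 or 2 of this group 3084 or 3074 passed. Without any 1 of the 3 samples the calls of Insig1, Mup3 and Mup4 ended, that of Insig1 also with software ratios and median centring, that of Mup3 with normexp and no filter and those of Mup3 and Mup4 on Cy3 arrays, and Spp1 was not called without replicate 1 or 3, with values of -3.09 to -1.43 over the settings. Of 174 genes with several called probes, 41 had probes called in opposite directions.

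The sexes differed in much the same genes with and without STAT5a. Of the probes called in wild-type and in knockout liver, 3459 were shared and 3455 of these had the same direction, where independent lists would share 343 higher and 359 lower probes. The ratios of both comparisons correlated at 0.79 across 19487 probes, which are not independent replicates, while a simulation without sex effects gave -0.01. Of the probes called in wild-type liver, 97.1% had the same sign in knockout liver, and their knockout ratio was 0.82 times the wild-type ratio by regression, while over the probes called in knockout liver the wild-type ratio was 0.88 times the knockout ratio, and both slopes rest on probes selected by their call. Both comparisons used different samples, and pairs of samples with different replicate numbers correlated at 0.58 on average.

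**Figure D1:**
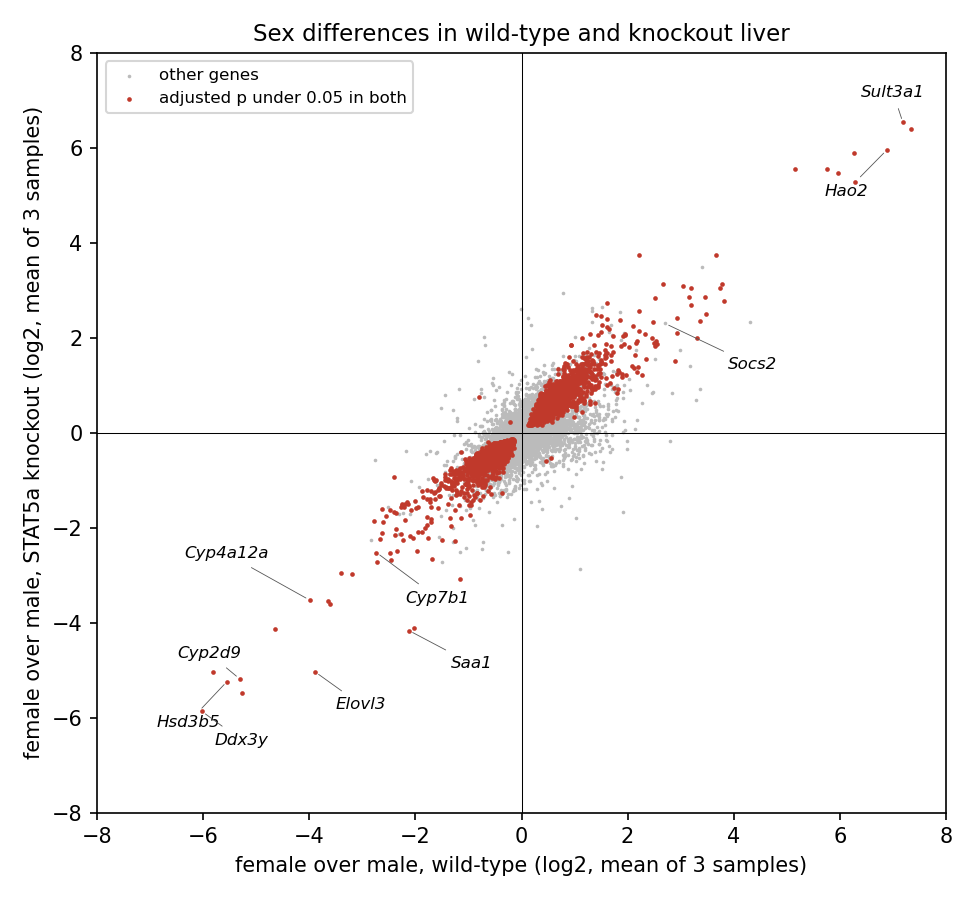
Female over male log2 ratio in wild-type liver (horizontal) against knockout liver (vertical), each the mean of 3 samples, with 1 point per gene. Red points passed the test in both comparisons, with Ddx3y at -6.02 and -5.87 and Sult3a1 at 7.19 and 6.54.

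**Figure D2:**
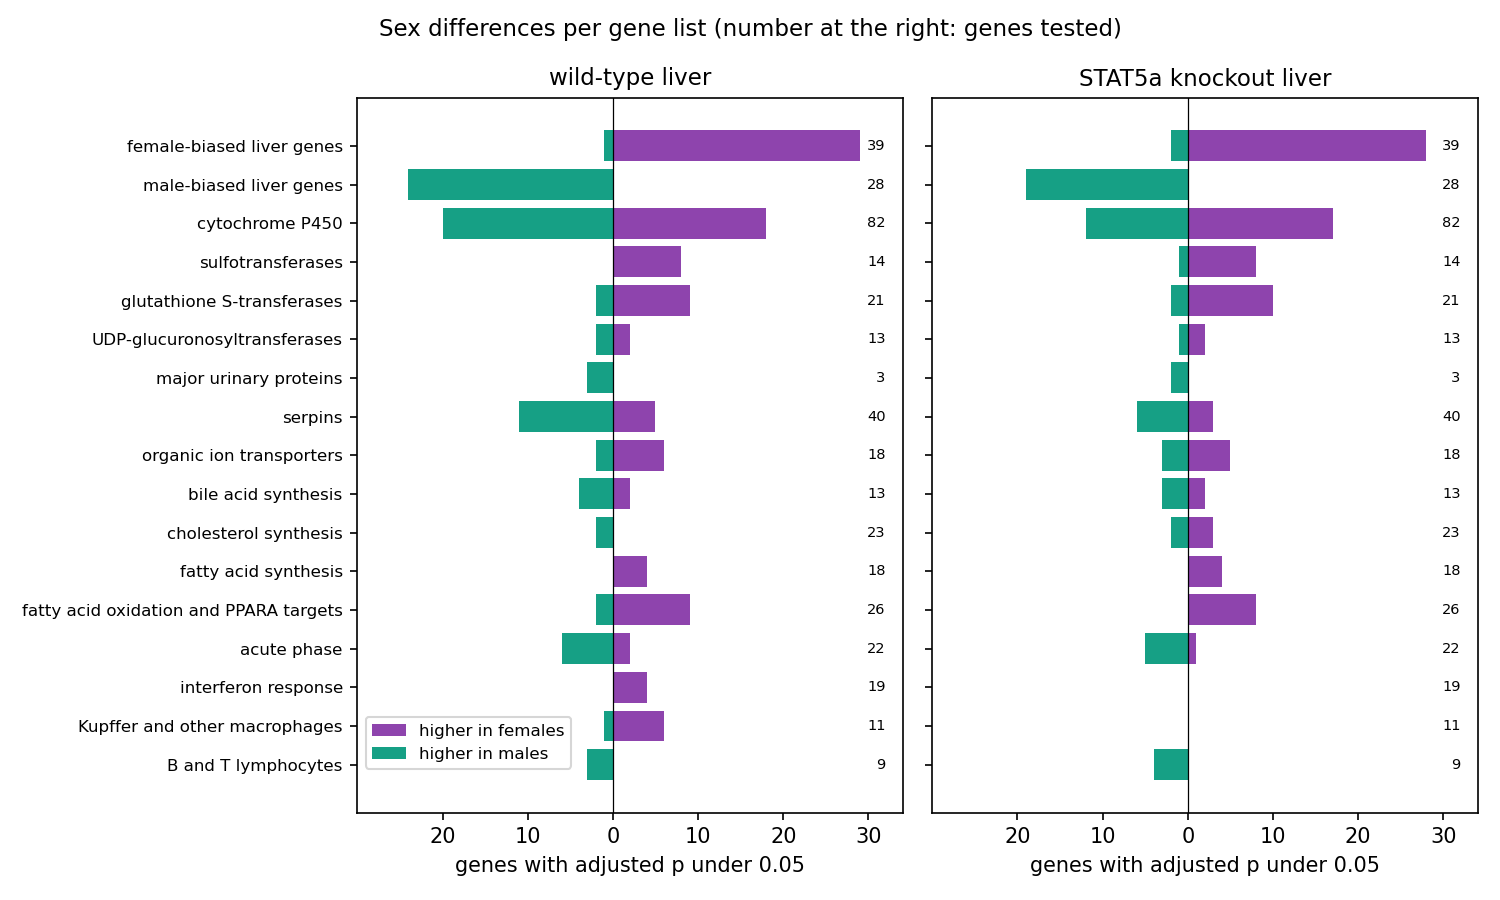
Number of genes per list higher in females (bars to the right) or higher in males (bars to the left) at a limma adjusted p under 0.05, in wild-type and in knockout liver. The male-biased list held 24 and 19 genes higher in males of 28 tested, and the female-biased list 29 and 28 genes higher in females of 39.

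The test of the difference between both sex comparisons asked whether STAT5a changed a sex difference. By limma, 0 probes passed, with 1459 at an unadjusted p under 0.05 and 974 expected by chance. Among glutathione S-transferases, Gstp3 differed by -1.60 (SE 0.43) between wild-type and knockout sex ratios, with an adjusted p of 0.52 over all probes and 0.029 adjusted over the list alone. Gstm2 differed by -1.04 (SE 0.22), with 0.51 and 0.019. Macrophage markers differed the other way, with Marco at 3.58 (SE 1.20) and Cd5l at 1.85 (SE 0.66), adjusted p of 0.62 and 0.64, and 0.0496 and 0.0499 adjusted over the list alone. For Stat5a the difference was 0.49 (SE 0.52, adjusted p = 0.82), and for Stat5b no value is given, since its knockout sex ratio lay at background.

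The comparison of knockout with wild-type females asked which transcripts depend on STAT5a in female liver. Stat5a was lower in the knockout in 3 of 3 samples, at a log2 ratio of -2.65 (SE 0.37) or 6.29-fold, with an adjusted p of 0.080, which was 0.037 with the replicate number as a block and 0.23 in the loop model. Psmd9, which encodes an assembly chaperone of the proteasome, rose by 0.60 (SE 0.06) or 1.51-fold, in 3 of 3 samples with an adjusted p of 0.040. The acute-phase genes Saa1, Saa2 and Saa3 had ratios of -2.24 (SE 0.47), -2.04 (SE 0.35) and -2.25 (SE 0.48), with adjusted p of 0.30, 0.17 and 0.30. Macrophage markers had ratios below 0, with the scavenger receptor gene Marco at -2.45 (SE 0.85), Cd5l at -1.26 (SE 0.46), C1qa at -1.16 (SE 0.41) and Adgre1 at -1.15 (SE 0.47).

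By limma 2 probes passed over all probes, both for Psmd9, while 1520 had an unadjusted p under 0.05 and 974 were expected by chance. For this comparison the simulations with no effect gave 0.45 calls on average and at most 3, a range that holds the 2 calls. With the replicate number as a block 4 probes passed, of which 1 was among these 2, and in the loop model 0 passed. Psmd9 was not called in the fit on the 3 samples of this group or with no intensity filter (0 probes each). Of the 12 fits that left out 1 sample of any group, Psmd9 was called only without replicate 1 of this group or replicate 1 of the knockout sex comparison (2 probes each). Without replicate 2 of this group 0 probes passed, and without replicate 3 the 3 probes that passed were others. Of 11 macrophage markers, 0 passed over all probes and 8 were lower adjusted over the list alone, with a list median of -0.94 and a fry p of 0.030, which was 0.39 adjusted over 33 lists. Of 22 acute-phase genes, 0 passed over all probes and 3 were lower adjusted over the list alone, Saa1, Saa2 and Saa3. The list of the growth hormone and STAT5 axis, which holds Stat5a itself, had a mixed fry adjusted p of 4.3e-04 with Stat5a and 0.22 without it (a run added after the data had been seen), and held Stat5a as lower and Serpina1a, at 0.53, as higher adjusted over the list alone. Stat5b had a ratio of -0.07 (SE 0.06, adjusted p = 0.82).

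With 2 of 19487 probes past the test in knockout females, counts of 0 say little about any list. Of 28 male-biased genes, 0 passed over all probes and 1 was higher adjusted over the list alone, the epidermal growth factor receptor gene Egfr at 1.24 (SE 0.25). Of 39 female-biased genes, 0 passed over all probes and 1 was lower adjusted over the list alone, Acot3 at -0.87 (SE 0.13). Among lymphocyte genes Cd79b at -0.50 (n = 2) and Ms4a1 at -0.28 were lower adjusted over the list alone, and the bile acid conjugating enzyme gene Baat was so at -0.37. No list passed the directional fry test, with adjusted p of 0.39 or more. Interferon response genes had a list median of -0.74 with 0 of 19 past the test (0 adjusted over the list alone), and by sample it was -0.35, -1.64 and -0.20. At a fold of at least 1.5 in each of 3 samples, 81 genes were lower and 22 higher, while other sign settings of the samples gave 23 to 75 such genes in all, and at a fold of at least 2 these were 13 and 4 genes against 4 to 22.

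The comparison of knockout with wild-type males asked the same in male liver. Stat5a had a log2 ratio of -1.96 (SE 0.37) or 3.89-fold, lower in 3 of 3 samples, with an adjusted p of 0.22. Actr2, which encodes a subunit of the actin-nucleating Arp2/3 complex, fell by 1.48 on the log2 scale (SE 0.14, 2.78-fold, 3 of 3 samples) with an adjusted p of 0.017. Mt2, a metallothionein that binds zinc and copper, had a ratio of 1.76 (SE 0.33), with an adjusted p of 0.22 over all probes and 0.0081 adjusted over the list alone. Saa1 and Saa2 had ratios of 0.71 (SE 0.47) and 0.86 (SE 0.35), Cd5l of 0.65 (SE 0.46) and Marco a fold of 2.83 (log2 SE 0.85, from 0.66 to 2.19 on the log2 scale over the settings), with adjusted p of 0.84, 0.69, 0.86 and 0.80.

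By limma 1 probe passed, that of Actr2, while 1327 had an unadjusted p under 0.05 and 974 were expected by chance. For this comparison the simulations with no effect gave 0.45 calls on average and at most 2, a range that holds the 1 call. With the replicate number as a block 0 probes passed (1882 at an unadjusted p under 0.05), and Actr2 had an adjusted p of 0.072, or 0.18 in the loop model. Of the 12 fits that left out 1 sample of any group, Actr2 was called only without replicate 1 of this group and without replicate 1 or 2 of the female genotype comparison (1, 3 and 1 probes), and without replicate 2 or 3 of this group 0 passed. Over the single lists, 2 male-biased genes were lower adjusted over the list alone, Cyp4a12a at -0.59 and Cyp4a12b at -0.31, with 0 of 28 past the test over all probes. Insig1, a brake on cholesterol synthesis, was at -1.11 (SE 0.26) and lower adjusted over the list alone, with 0 of 23 genes of its list past the test over all probes. Cpt1a, the gatekeeper of mitochondrial fatty acid oxidation, was at 0.65 and higher adjusted over the list alone, as were Stab1 at 0.33, Ighm at 0.36 and Cd3e at 0.22. Heat shock genes had the ratios -1.16 for Hsp90aa1 and -1.16 for Hspa1a, with 0 of 15 past the test (0 adjusted over the list alone). At a fold of at least 1.5 in each of 3 samples, 17 genes were lower and 32 higher, against 11 to 22 in all in other sign settings, and at a fold of at least 2 these were 3 and 1 against 2 to 4. No list passed the directional fry test, with adjusted p of 0.34 or more, and the growth hormone axis had a mixed p of 0.40 before adjustment. Stat5b had a ratio of -0.03 (SE 0.06, adjusted p = 0.98).

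**Figure D3:**
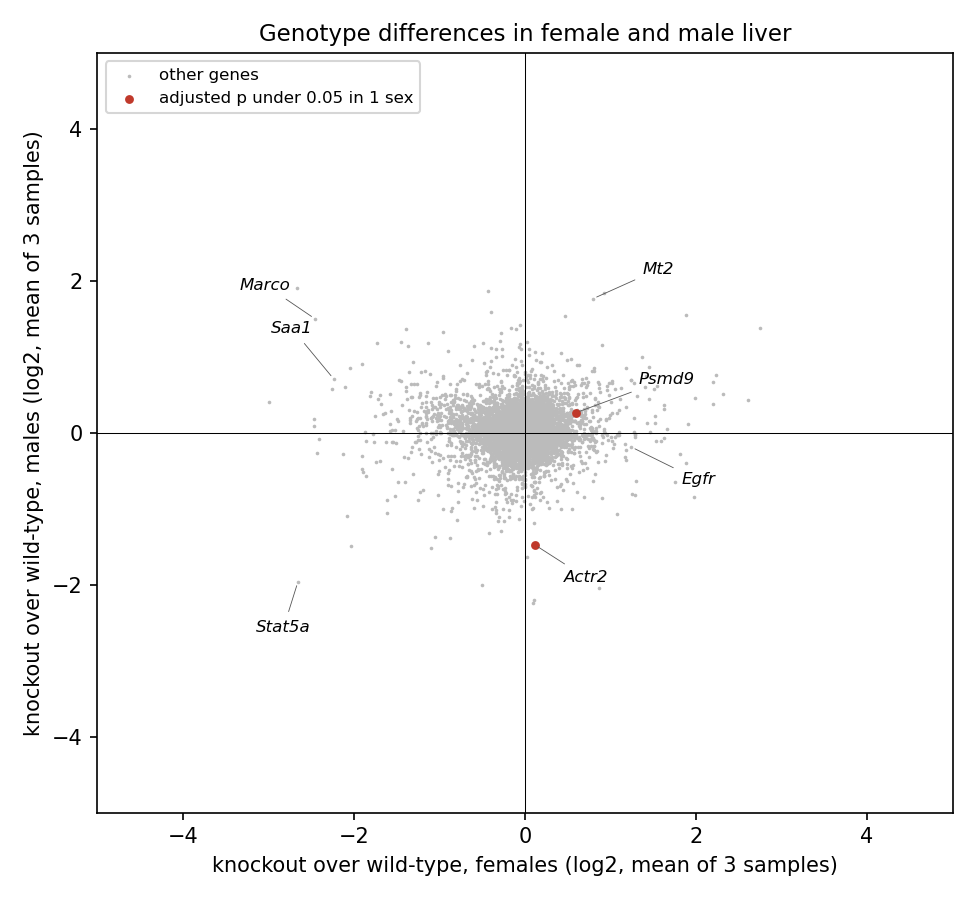
Knockout over wild-type log2 ratio in females (horizontal) against males (vertical), each the mean of 3 samples, with 1 point per gene. Stat5a lies at -2.65 and -1.96, and the red points mark Psmd9 (females) and Actr2 (males), the genes past the limma threshold in 1 sex.

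**Figure D4:**
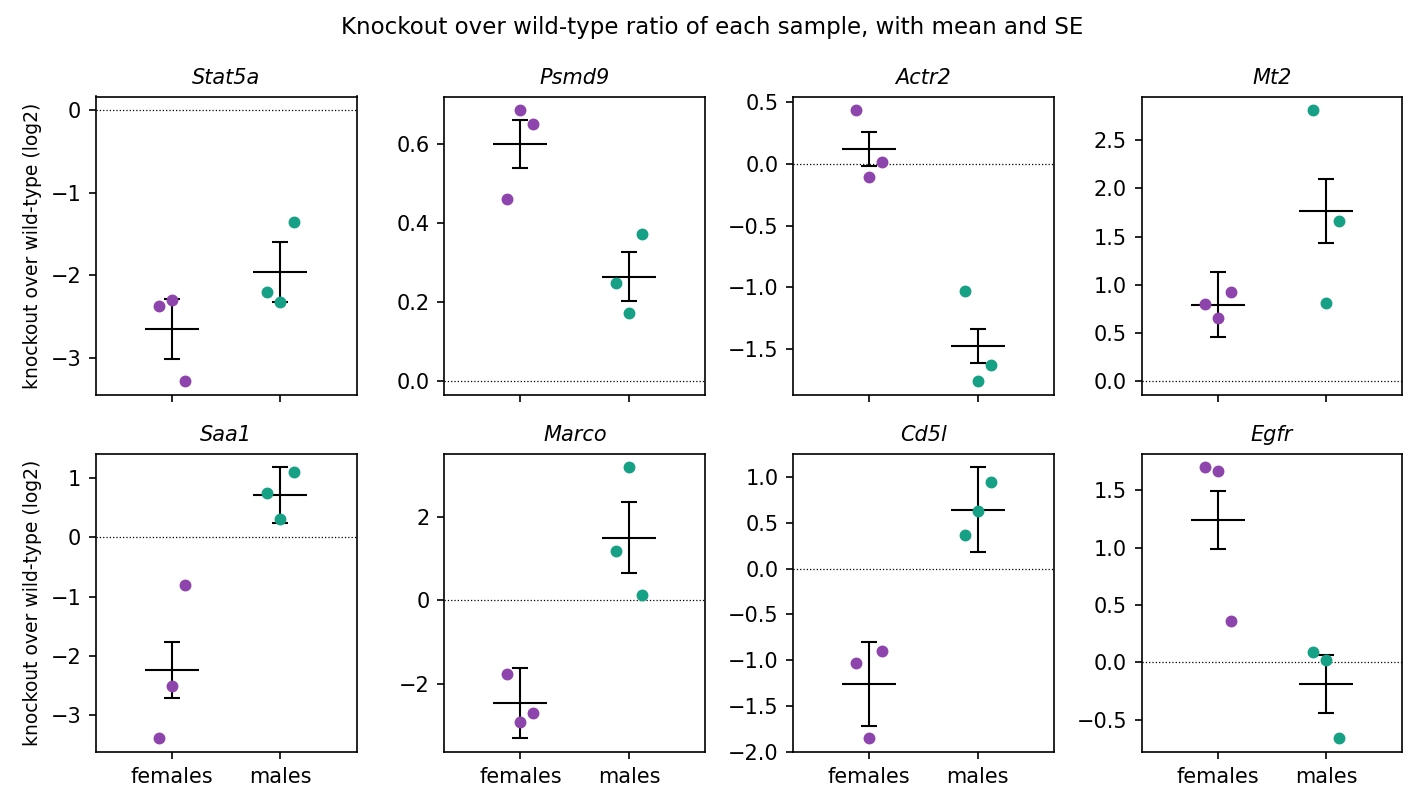
Knockout over wild-type log2 ratio of 8 genes in each of 3 female and 3 male samples (points), with the group mean (bar) and the SE of the limma fit (whiskers). Stat5a was below 0 in all 6 samples, while Saa1, Marco and Cd5l were below 0 in the 3 female samples and above 0 in the 3 male samples.

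The test of the difference between both genotype comparisons asked whether the knockout acted differently in the sexes. By construction this is the difference between both sex comparisons with its sign turned, measured on other arrays of the same animals. Similar values in both tests are therefore a repeated measurement and not independent support. By limma 0 probes passed, with 1223 at an unadjusted p under 0.05 and 974 expected by chance. Saa2 differed by -2.90 (SE 0.50), Saa1 by -2.94 (SE 0.66) and Saa3 by -2.83 (SE 0.67), with adjusted p of 0.56, 0.64 and 0.64 over all probes, and the 3 genes passed adjusted over the list alone. Marco differed by -3.95 (SE 1.20, adjusted p = 0.71) and Cd5l by -1.91 (SE 0.66, adjusted p = 0.75), and both passed adjusted over the list alone, where 4 of 11 macrophage markers passed below 0 and 1 above 0, Cd68 at 0.22. Gstp3 differed by 1.55 (SE 0.43) and Gstm2 by 1.09 (SE 0.22), with adjusted p of 0.70 and 0.63 over all probes, and 0.034 and 0.014 adjusted over the list alone. For Stat5a the difference was -0.69 (SE 0.52, adjusted p = 0.84). For Stat5b it was -0.03 (SE 0.09, adjusted p = 0.96), from a probe near background that says little.

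The overlap of sex-biased probes with probes called between genotypes asked whether the knockout moved sex-biased genes. Of the 5187 sex-biased probes of wild-type liver, 0 were called in female knockouts and 1 in male knockouts, that of Actr2, where independent lists would share 0.532 and 0.266, so with 2 and 1 calls in all the counts decide little. Actr2 was lower in wild-type females than in wild-type males and fell in knockout males. Both comparisons share the wild-type males, so a high value in those animals alone would give both results. Knockout over wild-type females was 0.44, -0.10 and 0.02 by sample. With the replicate number as a block the counts were 2 and 0. The female knockout ratios correlated at -0.34 with the wild-type sex ratios across probes, against -0.46 in a simulation with no effect in which the wild-type females were shared. The male knockout ratios correlated at 0.21, against 0.46 in the simulation with shared males. That simulation held no sex effect, unlike the data, so the sizes of these correlations cannot be compared. The covariance was -0.044 against a simulated -0.020 in females, and 0.020 against 0.020 in males. Between samples of different replicate numbers the correlations were -0.07 and 0.07 on average. The covariances there were -0.017 (-0.039 to 0.002) and 0.012 (-0.007 to 0.042). Of the sex-biased probes, 31.4% had the sign of their sex ratio in female knockouts and 61.8% in male knockouts. Shared wild-type animals push both shares in these directions.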

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

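All tests of this part that weigh an explanation were chosen after the results had been seen. Among 14 genes and 33 lists, those were picked out whose 3 female and 3 male samples went opposite ways in the knockout, or whose sex difference did so between genotypes. The 14 genes, apart from Stat5a and Stat5b, had already been named for their values in the genotype comparisons, so their picks are no support. Both kinds of comparison rest on the same animals and some lists share genes, so the picks are not independent. By this rule itself the difference was not tested, and chance gives it for 3.125% of cases in each of both comparisons, or 2.06 of 33 lists over both, where 4 were picked. The limma test of the difference between the sexes passed for 0 of 19487 probes (1223 at an unadjusted p under 0.05).

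Knockout over wild-type, females minus males, was -2.94 for Saa1, -2.90 for Saa2 and -2.83 for Saa3, with limma adjusted p of 0.64, 0.56 and 0.64. It was -3.95 for Marco, -1.91 for Cd5l and -1.49 for Adgre1, with adjusted p of 0.71, 0.75 and 0.79. By the list median in each sample, averaged over samples, the lists differed by -0.54 for acute phase, -1.17 for Kupffer and other macrophages and 0.23 for male-biased liver genes. For blood, the sex difference of wild-type minus that of knockout liver was -0.62 in the same way. The fry tests of these 4 differences, in that order, gave p of 0.11, 0.058, 0.034 and 0.23, and 0.65, 0.64, 0.56 and 0.63 adjusted over 33 lists.

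Macrophage markers had a median of -0.94 over 11 genes in knockout over wild-type females, with 0 of 11 called over all probes and a fry adjusted p of 0.39. Interferon response genes went the same way, with a median of -0.74 (-0.35, -1.64 and -0.20 by sample), so a shared immune state of the animals was not set apart. A lower share of all cells other than hepatocytes would lower the markers of endothelium, stellate cells and bile duct too, and their median was 0.11. By list the median was 0.06 for endothelium, -0.02 for stellate cells and 0.32 for bile duct. The mean of the stellate list was -0.32, and 3 of its 7 genes had values in all 12 samples, so the pooled median is a limited measure. The largest macrophage ratio was in the sample of wild-type female 2 (-1.38), yet without the 2 samples of that animal the median was -0.81, so that animal alone is not the whole cause. An effect of the genotype may remain, as an untested hypothesis.

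Saa1, Saa2 and Saa3 had a median of -2.24 in knockout over wild-type females. A milder acute-phase state as a whole could lower other genes of that list as well: the median of 17 others was -0.21, with 6 lower in 3 of 3 samples, and with the metallothioneins Mt1 and Mt2, which that median left out, -0.13 over 19, which leaves this open. The values of Saa1 and Saa3 differed by at most 0.24 over 12 samples, against a median difference of 0.40 between Saa1 and Saa2, so 1 transcript read by both probes cannot be told apart from 2 that go together. An effect of the genotype was not tested apart from these.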

How the results depend on the processing

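Raw signals with normexp, the removal of both samples of wild-type female 2 and all fits of the mean knockout effect over both sexes were chosen after the data had been seen. Sex differences kept similar counts with software ratios (5387 probes in wild-type and 5348 in knockout liver), the deposited table (5411 and 5292), normexp (5600 and 5071), and the stricter filter (4715 and 4657). By the first 2 of these the direction shifted toward males, with 2182 higher in females and 3205 in males in wild-type liver by software ratios and 2258 and 3153 by the deposited table, and 2510 and 2838, then 2547 and 2745, in knockout liver. The median female over male log2 ratio of all probes lay lower there too. In wild-type liver it was -0.030 and -0.029, against 0.008 with loess. In knockout liver it was -0.019 by both, against -0.001 with loess.

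On the samples of the groups compared alone, 1753 and 2992 probes differed between the sexes in wild-type and knockout liver, and 0 between genotypes in females, in males and over both sexes, with fewer samples to estimate the spread. With a fold of at least 1.5 besides, 1960 and 1916 differed between the sexes and 2 between genotypes over both sexes, by construction. In female genotype, median centring gave 1 and no filter 0. With the replicate block, 4 probes differed in female and 0 in male genotype and 77 over both sexes, and 2 and 0 of the sex-biased probes were among them. In the loop model the genotype counts were 0 in females, 0 in males and 1 over both sexes, and 0 sex-biased probes differed in male genotype. Without both samples of wild-type female 2, 3350 probes differed between the sexes in wild-type liver and 0 in male genotype, and 3 and 0 sex-biased probes differed in female and male genotype. Apart from the cases of fewer samples and of the fold, the cause was not tested.

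Arrays with the first-named liver in Cy5 alone gave 366 probes in female and 230 in male genotype, and 1298 and 865 in the tests between the sex and between the genotype comparisons. Arrays with it in Cy3 alone gave 263, 273, 1417 and 887. Most probes called in both orientations had opposite signs, a dye effect that the swap cancels, and for those called in 1 this was not tested: of 107 in female genotype 91 had opposite signs and of 107 in male genotype 89, of 532 between the sex comparisons 517 had opposite signs, and of 396 between the genotype comparisons 382 had.

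Leaving out 1 sample gave 3167 to 5138 probes for sex in wild-type liver (lowest without female over male wild-type replicate 2), 3074 to 5209 in knockout liver (lowest without male over female knockout replicate 2), 0 to 3 for female and 0 to 3 for male genotype, 0 to 1 for each test between comparisons, 0 to 0 and 0 to 3 for sex-biased probes in female and male genotype, and 0 to 6 over both sexes. Without any 1 of the 3 male genotype samples, or without female genotype replicate 2, the count over both sexes was 0.

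Of 101 called gene values 65 stayed called in each setting run for them, 36 lost the call in some, and 0 reversed. Of 29 values not called, 10 of 451 settings had the opposite sign and 14 gave a call in the same direction. Stat5a was called in female genotype with the replicate block (adjusted p = 0.037), a fit whose p-values can be too small. It was also called in knockout sex on the samples of that comparison alone (0.049). The other calls came on arrays of one dye orientation: Stat5a (0.0077 and 0.0084) and Saa1 (0.049 and 0.047) on both in female genotype, Saa2, Saa3 and Egfr there on one, Stat5a in male genotype on Cy3 arrays (0.019), and Saa1 and Saa2 in the difference between genotype comparisons on both. Stat5a in wild-type sex became -0.076 on Cy3 arrays and -0.62 to 0.47 with 1 sample left out (lowest without female over male wild-type replicate 3). Its difference between sex comparisons became -0.18 to 0.90, lowest without the same sample. Stat5b became 0.026 in female genotype on Cy5 arrays, 0.14 in male genotype on Cy3 arrays and -0.073 to 0.014 in male genotype with 1 sample left out (highest without male genotype replicate 2). Its difference between genotype comparisons became 0.075 in the loop model, 0.23 on Cy5 arrays and -0.085 to 0.027 with 1 sample left out (highest without female genotype replicate 1, above 0 also without male genotype replicate 3). The cause was not tested, and the Stat5b probe lay near background.

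The fry calls of glutathione S-transferases in wild-type and sulfotransferases in knockout sex ended with software ratios (adjusted p = 0.051 and 0.062). Those of serpins and lymphocytes in wild-type sex, and of early response genes in knockout sex, ended in some fits that left out 1 sample. Signal over background limits low genes, as the bounds given for Sult2a2 and Elovl3 show. A run without background correction and a block for slide or scan date were not run.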

Other observations

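All tests of this part were chosen, or their predictions written, after the results had been seen. With 3 samples the 4 sign settings are too few for a share under 0.05. For sex in wild-type liver 1 of 4 settings reached the real 5187 probes (highest other 1), and in knockout liver 1 of 4 reached 5278 (highest other 3). For female genotype 1 of 4 reached 2 probes (highest other 0) and for male genotype 1 of 4 reached 1 (highest other 0). For sex-biased probes in female genotype the real count was 0, reached by 4 of 4, and in male genotype 1, reached by 1 of 4 (highest other 0 in both). The 10 splits of 6 samples are too few as well: both tests between comparisons had a real count of 0, reached by 10 of 10, with highest others of 0 for sex and 2 for genotype. The 4 splits that part every pair of one number gave at most 0, and the other 6 gave 0 to 2.

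The mean knockout effect over both sexes was added after the data had been seen. By limma 6 of 19487 probes passed, 3 higher and 3 lower, and 1 in the loop model, which kept Znrf3 alone. With the replicate block 77 passed, which included these 6. Its p-values leave out the shift between animals shared by one number and can be too small. Stat5a was at -2.31 (SE 0.26, adjusted p = 0.024), Pdia3, a disulfide isomerase of the endoplasmic reticulum, at -0.75 (SE 0.09, adjusted p = 0.039) and Hipk2 at -0.51 (SE 0.07, adjusted p = 0.045). Znrf3, a brake on Wnt signalling, was at 0.51 (SE 0.05) and Psmd9, with 2 probes, at 0.43 (SE 0.04), both with an adjusted p of 0.017. In the loop model the adjusted p was 0.074 for Stat5a and Psmd9, 0.13 for Pdia3, 0.16 for Hipk2 and 0.049 for Znrf3. Each of these 5 genes had its direction in 6 of 6 samples and was chosen after its values were seen. Of 32 sign settings of the 6 samples 1, the real one, gave as many calls (highest other 4), but these calls include Stat5a, the targeted gene, and 2 probes of Psmd9. Counted as genes other than Stat5a, 2 of 32 settings gave as many (real 4, highest other 4), so for these genes chance was not excluded. Stat5a, Pdia3 and Hipk2 lost the call without any 1 of the 6 genotype samples, and Psmd9 without any of them but female replicate 1. Stat5a also lost it with normexp, Hipk2 with median centring, no filter and arrays of either dye orientation, and Pdia3 and Znrf3 on Cy5 arrays, in all 10 of 18 settings for Stat5a and for Pdia3, 13 for Hipk2, 8 for Psmd9 and 6 for Znrf3. Without any 1 male genotype sample, or female genotype replicate 2, the count was 0.

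Genes that differ the same way in knockouts of both sexes seemed frequent on chromosome 11, which holds Stat5a. This test followed several other looks at the same data: top lists of other lengths, each chromosome, and windows along chromosome 11. There were 33 of 1232 genes on it (2.68%) and 155 of 14339 elsewhere (1.08%). But 2 of 32 sign settings put as many on it (highest other 34, real 33), so chance was not excluded. A higher density of well measured genes might add to it, since opposite-direction genes gave an exact p of 0.27 against same-direction genes. Alleles carried along with the targeted gene could do so too, but nearer and farther genes (22 and 11 of 616 each) gave an exact p of 0.076, and 0 of the 20 nearest genes were among them, so this stays a hypothesis that the tests did not bear out.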
